A study of Homo sapiens with 6 samples.

How the data were processed

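The series measured RNA in single cells from differentiating cultures of H9, an established human embryonic stem cell line, whose genotype label names a green fluorescent protein reporter placed in the RAG1 gene. RAG1 encodes part of the recombinase that assembles antigen receptor genes in lymphocytes. The 6 libraries carry the labels day6, day12, day15, day19, day25a and day25b, with 1 library for each label. The labels name the 10x Genomics single cell 3' v2 protocol, but the kit version is in doubt from how the barcodes begin, and it was not checked against a list of that kit's barcodes. The labels do not say what the letters a and b stand for, so day25a and day25b were kept as separate labels.

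The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. Cell Ranger 6.1.1 made the matrices, per the file headers. The genome build was hg38, per the submitters' processing notes. The annotation release, the treatment of introns and the rule for calling cells are not given in the sources used here. The other deposited files hold gene identifiers with their symbols and barcode sequences, which only name the entries of each count matrix, per the file headers. Genes were taken by the symbols that the files pair with their Ensembl identifiers, over 33694 features. All 226 members of the 18 fixed gene lists and all 191 cell type markers were matched, 1 of them through another symbol.

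Depth differed between libraries. The deposited totals were 178915252 UMIs over 11783 barcodes for day6, 141888125 over 7135 for day12, 130745581 over 10296 for day15, 127751763 over 9470 for day19, 112748986 over 8047 for day25a and 108517784 over 8542 for day25b. Barcodes were kept with at least 500 detected genes and at most 20% mitochondrial counts, which left 11486, 6398, 9385, 6603, 6427 and 5998 cells in that order, or 97.5%, 89.7%, 91.2%, 69.7%, 79.9% and 70.2% of the barcodes. Doublets were predicted in each library by Scrublet as run in scanpy, with its automatic threshold, and 487, 346, 373, 246, 259 and 288 cells were left out. For day25b the automatic threshold marked 2 cells (0.0333%), so the highest scores were left out at a rate of 0.8% per 1000 cells. The 44298 remaining cells entered all results.

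Cells of all libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log transformed, 3000 variable genes were standardised, and 50 principal components with 15 neighbours gave 26 Leiden clusters at resolution 1.0. A cluster took the name of the class for which the largest share of fixed markers was at least 2-fold higher than in the other cells and detected in at least 10% of its cells, with at least 3 such markers and a larger share than any other class. Classes with markers were 18, and names carry the ending "-like" because they rest on markers alone. A class was compared on its own where no cluster of it had more markers of another class than of its own among its top 10 genes. Monocyte or macrophage (cluster 11), mast, eosinophil or basophil (cluster 14), and part of the T and natural killer (NK) class (clusters 21 and 25) did not meet this, so they were compared within broader unions, as was lymphoid progenitor (cluster 20), with 1 such gene of its own class and 1 of another. These unions were the haematopoietic-like cells, the myeloid-like cells and the lymphoid-like cells of clusters 20, 21, 22, 23, 24 and 25. Cluster 13 held lymphoid and progenitor markers side by side and was kept out of the lymphoid-like union by a rule set after its values were seen, so its share is given separately.

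For each library, counts were summed over the cells of the whole library, the endothelial-like cells or the haematopoietic-like cells and expressed as CPM, each gene's share of the counts scaled to a common total of 1e6. The 13 planned comparisons set consecutive labels against each other, each of day25a and day25b against day19 in blood cells, and day25a against day25b. Within a class, consecutive meant among libraries with at least 100 of its cells. Endothelial-like cells of day19 were thus set against day12, and those of day25a against day19. The plan took day 25 libraries as blood cells only, so it did not foresee this comparison of day25a. A gene was called higher or lower when its CPM plus 1 differed at least 2-fold and its larger CPM was at least 10. There were no replicates, so no test between libraries was possible, and every difference compares libraries and not conditions. Intervals are 95% exact Poisson intervals for CPM and exact Clopper-Pearson binomial intervals for shares, and they cover counting error only. Where a count was 0, a limit of 3 counts was used over the cells of that library, for shares and for folds alike. Such folds are given as at least, and divide CPM by that limit without the added 1. The named genes of each comparison are the 10 highest and the 10 lowest log2 ratios of CPM plus 1 among genes whose larger CPM was at least 50, leaving out mitochondrial genes, ribosomal protein genes and features with clone-style or LINC names. Members of the fixed lists, the cell type markers, the genes of the share result and the 5 genes with the largest fold in each cluster may also be named. Near-identical genes, such as HBG1 and HBG2, HBA1 and HBA2, KRT81 and KRT86, XCL1 and XCL2, CCL3L3 and the HLA genes, share sequence, and their separate values are uncertain.

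The fixed lists covered arterial endothelium, venous and lymphatic endothelium, haemogenic endothelium with the endothelial-to-haematopoietic transition, a blood stem cell signature, the HOXA cluster, lymphoid commitment, T, NK and innate lymphoid genes, embryonic and fetal globins, embryonic and fetal RNA binding, the retinoid pathway, the Notch pathway, S phase, G2 and mitosis, MHC class II, hypoxia and glycolysis, interferon response, immediate early genes with dissociation stress, and extracellular matrix. For each list the median log2 ratio is given with an order-statistic interval over its members, the counts of members higher, lower or neither, and its percentile among 10000 random lists of the same size matched on mean expression. Members below 1 CPM in both libraries were not measured. For the list medians taken through the alternatives, where members had 0 counts in one library the median is also given with these at their bound, a step added after the results were seen. Values of 2 single genes are not reported here. All lists were computed in all comparisons. The 37 list medians taken through the alternatives were chosen after the medians were seen. Percentiles describe these libraries and are not p-values.

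Shares of cells with a UMI of RUNX1, RAG1, IL7R, CD7, DNTT, MYB, GFI1, DLL4, GJA5 and HOXA9 were computed after each cell was thinned to 4000 UMIs, leaving out shallower cells. For each gene the share in a cell class that should lack it is given as background, where such a class had at least 100 cells. Myeloid-like cells were added as such a class after the results were seen.

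The calling rule and the list percentile were tested on simulated data for blood cells of day12 against day6. Of 67 genes changed 1.5-fold 0% were called, of 67 changed 3-fold 100% and of 66 changed 4-fold 100%, while 0 of 8481 unchanged genes were called. The simulated counts held Poisson counting error alone, around a mean shared by both libraries, and changed genes lay well above the 10 CPM minimum. These outcomes were therefore nearly set by the rule. They do not show how often calls between single libraries reflect variation between libraries. A planted list of 15 genes reached percentile 100, and 4 of 100 random lists lay outside the central 95%.

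Lists, markers, comparisons (but for that of endothelial-like cells of day25a), the rule for named genes and most other settings tried were fixed before the data were examined. These other settings were a stricter cell filter (at least 1000 genes and at most 10% mitochondrial counts), keeping predicted doublets, Leiden resolutions of 0.5 and 2.0, 1500 variable genes with 30 components, median-of-ratios scaling, CPM without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, a pseudocount of 5 CPM, a larger CPM of at least 50 or no minimum, and thinning to 2000 UMIs or none. Alternatives that leave out day15 or day25a were added after the values were seen, and day25b against day19, used as one of them, was itself a planned comparison.

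Computation used python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and matplotlib 3.10.9.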

Results

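RNA of single cells was counted in 6 libraries from H9 human embryonic stem cells that had been differentiated towards arterial and blood-forming endothelium and then towards lymphoid cells. The libraries carried the labels day6, day12, day15, day19, day25a and day25b, 1 library each, and no treatments were compared. According to the design text, the series spans the formation of haemogenic endothelium, the vessel lining that gives rise to blood, through to lymphoid commitment, and the day 25 samples hold haematopoietic cells alone. The median depth per barcode was 13882 UMIs for day6, 16865 for day12, 11141 for day15, 10709 for day19, 10532 for day25a and 9940.5 for day25b. Medians of detected genes ranged from 3061.5 in day25b to 4586 in day12. After filtering, 10999, 6052, 9012, 6357, 6168 and 5710 cells remained in that order. There were no replicates, so all differences are between single libraries, and 95% intervals cover counting error only. Blood cells held 4425838 UMIs in day6, 41697376 in day12, 118997594 in day15, 40612655 in day19, 32301710 in day25a and 93175493 in day25b, and endothelial-like cells 80582231 in day6, 48724866 in day12, 32971474 in day19 and 35514110 in day25a. The day6 blood cells carry the least depth. In each comparison the library named first is given first, as CPM of that library against CPM of the other, and folds are ratios of CPM plus 1. Only folds over 0 counts, given as at least, divide CPM by the CPM of 3 counts without the added 1, so they cannot be set beside the others.

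The first question was which cell types each library held. Endothelial-like cells, marked by genes such as CDH5 and ERG, made up 53.7% (95% interval 52.8 to 54.7) of day6 cells and 48.2% (46.9 to 49.5) of day12 cells. They made up 28.8% (27.7 to 29.97) of day19 and 27.4% (26.3 to 28.6) of day25a. None were found among 9012 cells of day15 or 5710 cells of day25b, which allows shares of up to 0.0333% and 0.0525%. Haematopoietic-like cells made up 2.42% (2.14 to 2.72) of day6, 28.9% (27.8 to 30.1) of day12, 45.5% (44.3 to 46.7) of day19 and 52.4% (51.2 to 53.7) of day25a. In day15 and day25b they were nearly all cells, at 99.99% and 99.95%. Mesenchymal-like cells, rich in fibrillar collagens, made up 21.3% (20.3 to 22.4) of day12, 25.4% (24.3 to 26.5) of day19 and 19.9% (18.9 to 20.9) of day25a, and at most 0.600% of the other libraries. Epithelial-like cells, named from the keratins KRT8, KRT18 and KRT19, made up 42.6% (41.7 to 43.6) of day6 and at most 0.446% elsewhere, although EPCAM stood at 5.40 CPM and CDH1 at 0 in the whole day6 library. Cardiomyocyte-like cells did not exceed 1.09% in any library. The library labelled day25a held these non-blood cells although the design text gives day 25 as blood alone, and the library labelled day15 held almost none. Whether cells were sorted before loading is not stated for day15. The day6 share of blood cells was between 0.427% and 0.973% with predicted doublets kept or at the other clustering resolutions.

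**Figure D1:**
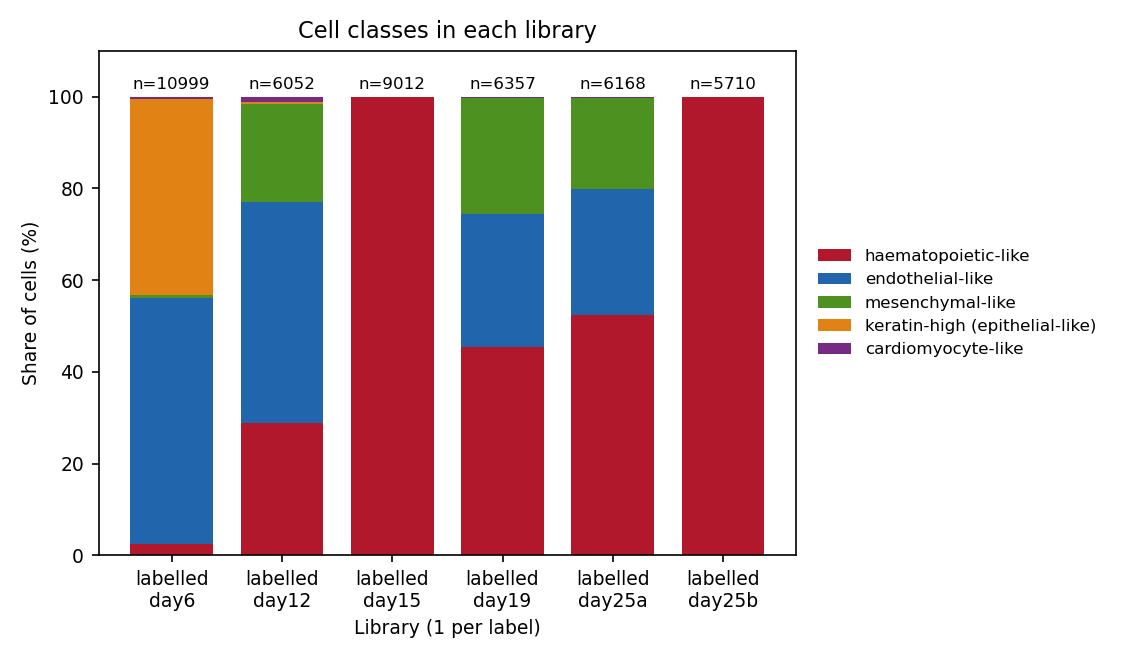
Stacked bars give the percent of cells (vertical axis) of each broad class in the 6 libraries (horizontal axis), with the number of cells above each bar. Haematopoietic-like cells reach 99.99% in the library labelled day15 and 99.95% in day25b, and 52.4% in day25a.

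Within the haematopoietic-like cells, the classes differed between libraries. Progenitor-like cells (cluster 5) made up 96.6% (93.7 to 98.4) of the 266 blood cells of day6 and 36.0% (33.8 to 38.3) of the 1752 of day12, beside 29.7% (27.6 to 31.9) myeloid-like and 27.4% (25.3 to 29.6) megakaryocyte-like cells. Lymphoid-like cells made up 0.228% of day12 blood, 95.7% (95.3 to 96.1) of the 9011 blood cells of day15, 2.63% (2.08 to 3.28) of the 2893 of day19, 15.7% (14.5 to 17.0) of the 3234 of day25a and 83.4% (82.4 to 84.3) of the 5707 of day25b. None were found in day6, which allows up to 1.13%. Cluster 13, in which lymphoid and progenitor markers stood side by side, held 3.20% (2.42 to 4.13) of blood cells in day12, 1.66% (1.41 to 1.95) in day15, 19.3% (17.9 to 20.8) in day19, 42.1% (40.3 to 43.8) in day25a and 3.43% (2.98 to 3.94) in day25b. In day25a, thinned to 4000 UMIs, CD7 had a UMI in 75% of cluster 13 and 67.4% of lymphoid-like cells. The shares were 47.2% and 43.5% for IL7R, 6.44% and 6.57% for RAG1, 19.95% and 19.1% for MYB, and 12.2% and 8.21% for RUNX1. The lymphoid-like share of day25a blood thus depends on where cluster 13 is placed. Myeloid-like cells made up 49.2% (47.4 to 51.1) of day19 and 31.5% (29.9 to 33.2) of day25a blood, and megakaryocyte-like cells 20.9% (19.4 to 22.4) and 10.1% (9.06 to 11.2). Erythroid-like cells were 9.72% (8.97 to 10.5) of day25b blood, 4.87% of day19, 3.42% of day12 and under 1% of day15 and day25a. Several clusters came almost wholly from 1 library and may stand for that library. These parts moved with the clustering: with 1500 variable genes and 30 components lymphoid-like cells were 55.5% of day25a and 16.65% of day19 blood, and erythroid-like cells 23.7% of day12 and 23.4% of day19. At resolution 2.0 lymphoid-like cells were 40.04% of day25a blood and progenitor-like cells 21.4%, against 27.8% of day19 blood, and at resolution 0.5 no cluster was named progenitor-like, and the myeloid-like share of day6 blood was 96.3%.

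**Figure D2:**
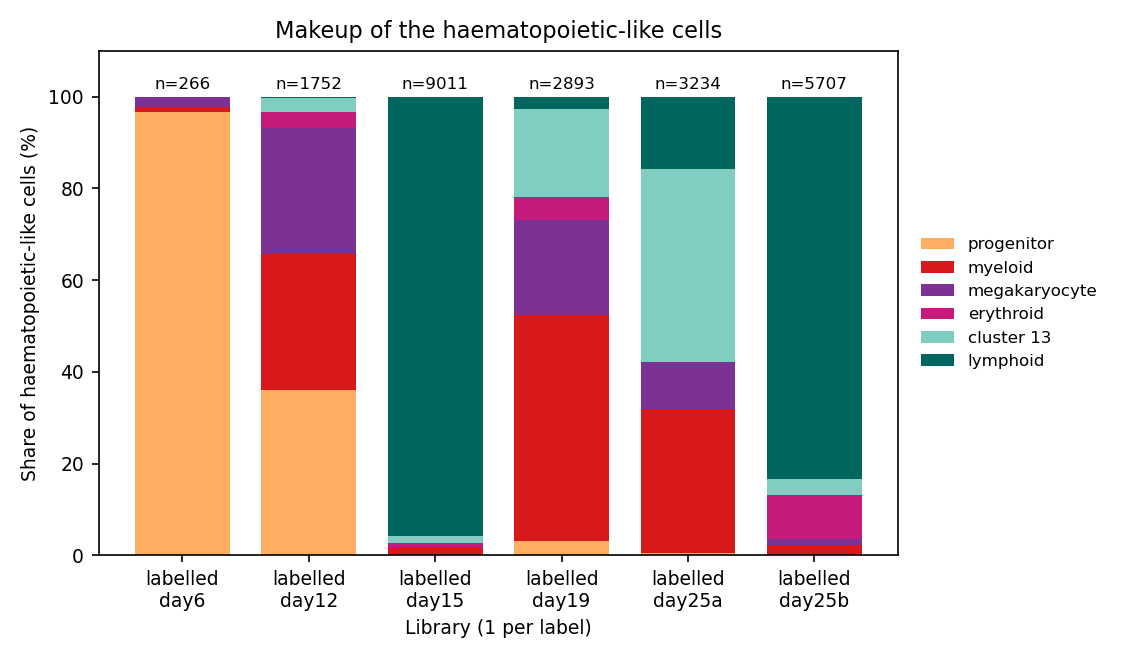
Stacked bars give the percent of the haematopoietic-like cells (vertical axis) in each part for the 6 libraries (horizontal axis), with the number of blood cells above each bar. Lymphoid-like cells make up 95.7% of blood cells in the library labelled day15, 15.7% in day25a and 83.4% in day25b. Cluster 13, which also held lymphoid markers and is drawn apart, makes up 42.1% in day25a.

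Whole libraries were compared first, and these differences include their makeup. Day12 against day6 asked what distinguished the culture with the larger share of blood cells. The higher side included genes of platelets and red cells. PF4, a platelet chemokine, stood at 399 CPM, 396 to 403, against 0.2303 CPM, 0.163 to 0.316, and PPBP, another platelet chemokine, at 683 against 1.13 CPM. The fetal and embryonic globins HBG2, HBE1 and HBZ were 263-fold, 167-fold and 151-fold higher in day12. CD74, the invariant chain of MHC class II, was 66.2-fold higher. On the lower side were SELE, which encodes E-selectin of activated endothelium, at 1.56 against 164 CPM, and NPPB, a natriuretic peptide, at 0.994 against 59.03 CPM. There too were keratins of simple epithelia, KRT8 at 166 against 1394 CPM, KRT18 at 383 against 2903 CPM and KRT19 at 12.02 against 149.9 CPM. In all, 784 of 9512 genes were at least 2-fold higher and 270 lower. In this and every other comparison the counts depended by construction on the 10 CPM minimum.

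Day15 against day12 and day19 against day15 set the lymphoid-rich library against its neighbours in label order. In day15, GZMB, a protease of cytotoxic granules, stood at 664 against 0.469 CPM, CD247, the zeta chain of the T cell receptor complex, at 597 against 0.437 CPM, and CD3G, another chain of that complex, at 1636 against 11.01 CPM. PRF1, encoding perforin, was 124-fold higher and LCK, a kinase of T cell signalling, 149-fold higher. Among the lower genes, COL1A1 stood at 0.101 against 1004 CPM, COL4A1 of basement membranes at 0.0924 against 1335 CPM, and the contractile gene TAGLN at 1.75 against 1503 CPM. In day19 against day15, COL1A1 stood at 2565 against 0.101 CPM, SPARC at 1817 against 0.949 CPM, GZMB at 0.433 against 664 CPM and TRBC1, a T cell receptor constant region, at 3.24 against 464 CPM. Day15 differed from day12 in 3338 genes (1260 higher, 2078 lower, of 10072) and day19 from day15 in 3386 (1951 higher, 1435 lower, of 10001). With day15 left out, day19 differed from day12 in 243 genes, 170 higher and 73 lower, so that both counts rest on the library labelled day15.

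The arterial character of the endothelium was compared within endothelial-like cells, which came from clusters 1 and 2 in day6 and mostly cluster 9 in day12. Of 20 arterial genes 7 were higher in day12, 1 was lower and 12 were neither, with a median log2 ratio of 0.63 (-0.05 to 1.04) at percentile 100 of matched lists. GJA5, the connexin of arterial endothelium, stood at 952 CPM, 943 to 961, against 144 CPM, 141 to 146, GJA4, another arterial connexin, at 609 against 223 CPM, and CXCR4, a chemokine receptor, at 611 against 193 CPM. The lower gene was SOX17, an arterial transcription factor, at 94.3 against 320.3 CPM, while the Notch ligand DLL4 stood at 192 against 193 CPM and its target HEY1 at 295 against 306 CPM. The extracellular matrix list had a median of 0.73 (0.49 to 1.16; percentile 99.99; 4 higher, 0 lower, 10 neither), with COL4A1 at 2081 against 913 CPM and LAMA4 at 454 against 159 CPM. Its members COL1A1, COL1A2, COL3A1, LUM, DCN and POSTN are also mesenchymal markers. Mesenchymal-like cells made up 21.3% of day12 and 0.600% of day6, and RNA from them in endothelial-like cells was not tested. DNA replication genes were lower. The S phase list had a median of -1.37 (-1.52 to -1.04; percentile 0), with 12 of 14 members lower, among them MCM2 at 8.37 against 21.95 CPM, TYMS at 64.6 against 178 CPM and PCNA at 33.4 against 68.1 CPM. The G2 and mitosis list had a median of -0.23 (percentile 3.73), with 2 of 14 lower.

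Other fixed lists were compared in the same endothelial-like cells. Of 8 measured venous and lymphatic genes 1 was higher (LYVE1, a hyaluronan receptor, 285 against 18.7 CPM) and 2 were lower (APLNR, the apelin receptor, 2.46 against 53.2 CPM, and the lymphatic regulator PROX1, 4.597 against 13.2 CPM), with a median of 0.22 (percentile 80.9). The haemogenic list had a median of 0.49 (percentile 95.7), and its only member at least 2-fold higher of 13 was the potassium channel KCNK17, at 15.4 against 3.29 CPM, with RUNX1, the transcription factor that starts blood formation, at 16.2 against 10.9 CPM. The blood stem cell signature had a median of 1.04 (percentile 99.5), with 2 of 5 measured genes higher, MECOM at 250.1 against 122 CPM and MLLT3 at 17.8 against 5.51 CPM. HOXA genes, which mark position along the body axis, had a median of 0.63 (percentile 88.8) over 4 measured of 11, none of them 2-fold apart. Medians were -0.29 (percentile 6.62; 0 of 6 measured apart) for the retinoid pathway and -0.01 (percentile 42.4; 2 of 15 higher) for the Notch pathway, whose median was 0.02 without mitochondrial and ribosomal genes and 0.08 with the mean of per-cell CPM. Among the genes farthest apart were ACSM3, an acyl-CoA synthetase, 19.1-fold higher, PRND, a prion-like protein, 17.9-fold higher, and PGF, placental growth factor and a leading gene of cluster 12, 10.6-fold higher, against SELE, 100.8-fold lower, the carbonic anhydrase CA2, 49.97-fold lower, lipoprotein lipase LPL, 5.65-fold lower, and ID1, a target of BMP signalling, 6.26-fold lower. In all, 718 genes were higher and 356 lower of 9316. SELE, CA2, LPL, SOX17, ID1, APLNR, GJA4, GJA5, ACSM3, PRND and LYVE1 are also among the top 10 genes of the clusters that set these cells apart, so they are not independent of the clustering.

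**Figure D3:**
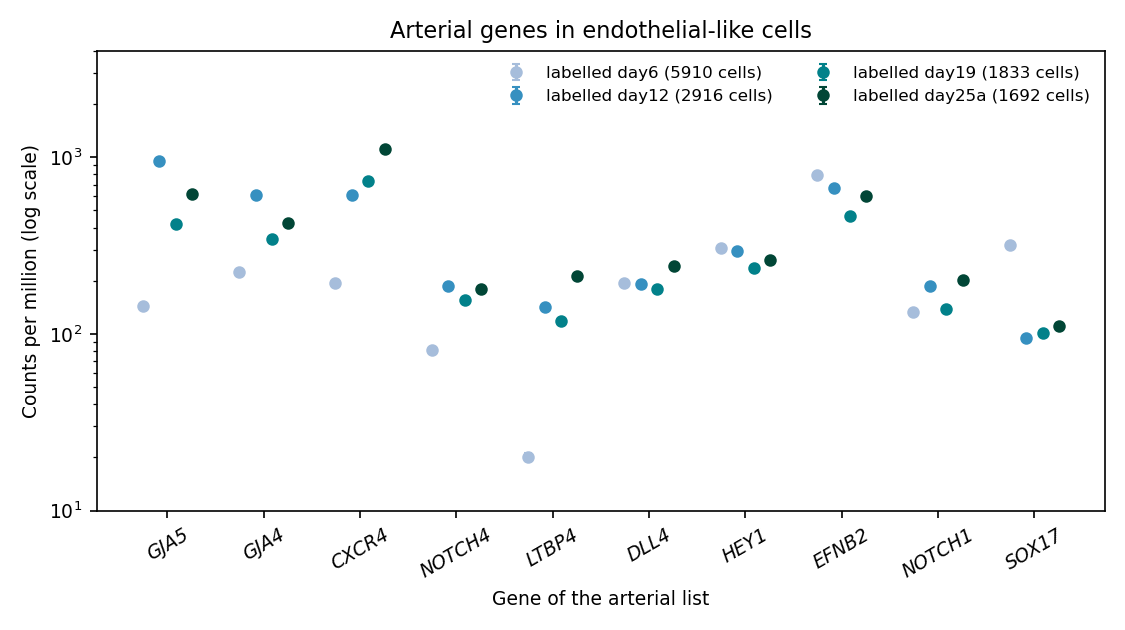
Points give the CPM on a log axis (vertical) of 10 arterial genes (horizontal) in endothelial-like cells of the 4 libraries that held them, with 95% exact Poisson intervals that are mostly narrower than the points. GJA5 stands at 144 CPM in day6 and 952 CPM in day12.

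Day19 endothelial-like cells (mostly clusters 9 and 12, with 224 cells in cluster 19) differed from day12 in few genes. Among the higher genes, the protease MMP10 stood at 381 CPM, 374 to 387, against 35.5 CPM, 33.9 to 37.2, the apelin peptide APLN at 1576 against 428 CPM, thrombospondin THBS1 at 744 against 187 CPM and CTGF at 426 against 94.2 CPM. The extracellular matrix list had a median of 0.45 (-0.10 to 0.64; percentile 100), with 0 of 14 higher and 0 lower. Here too RNA from mesenchymal-like cells, 25.4% of day19 and 21.3% of day12, was not tested as a source. TMEM100 was 6.61-fold lower, the interferon-induced BST2 5.64-fold lower, MMP9 5.402-fold lower and the TGF-beta co-receptor TGFBR3 4.85-fold lower. Arterial genes had a median of -0.29 (-0.51 to -0.13; percentile 0.10), with 0 of 20 higher and 2 lower, GJA5 at 417 against 952 CPM and HEY2 at 45.3 against 96.6 CPM. The blood stem cell signature had a median of -0.80 (percentile 0.0450), with 1 of 5 lower (MLLT3, 8.16 against 17.8 CPM). The embryonic and fetal RNA binding list, around LIN28B, had a median of -0.65 (percentile 0.010), with 1 of 5 lower (LIN28B, 10.8 against 29.6 CPM). Of 9038 genes 73 were higher and 136 lower. Median-of-ratios scaling, which shifted the median of all genes by 0.13, gave 99 and 93, and a pseudocount of 5 CPM gave 139 genes in all. MMP10 and APLN also lead cluster 12, which held 431 cells of day12 and 707 of day19. GJA5 leads cluster 9, which held 2444 and 902, so the arterial difference includes cluster makeup. The arterial median was -0.12 with the mean of per-cell CPM.

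Day25a endothelial-like cells came mostly from cluster 19 and day19 cells mostly from clusters 9 and 12. Genes of mitosis were lower in day25a. The proliferation marker MKI67 stood at 2.67 against 35.1 CPM, TOP2A at 3.998 against 34.4 CPM and the centromere protein CENPF at 4.56 CPM, 3.89 to 5.32, against 52.8 CPM, 50.3 to 55.3. Of the G2 and mitosis list 13 of 14 genes were lower, with a median of -2.24 (-2.83 to -2.09; percentile 0), and of the S phase list 5 of 14 were lower, with a median of -0.90 (-1.86 to -0.58; percentile 0). IGF2, a fetal growth factor, stood at 4732 against 754 CPM, DLK1, a membrane ligand of fetal tissues, at 1807 against 344 CPM, and the growth factor binding protein IGFBP3 at 272 against 70.1 CPM. Immediate early genes, which also respond to dissociation, had a median of 0.87 (0.26 to 1.39; percentile 100), with 5 of 10 higher, among them FOS at 49.5 against 11.8 CPM and JUNB at 249 against 93.4 CPM. Arterial genes had a median of 0.33 (0.16 to 0.55; percentile 99.99), with 2 of 20 higher, HEY2 at 104 against 45.3 CPM and IGFBP3. APLN was 3.82-fold lower, and ANKRD1 and CTGF, targets of YAP signalling, were 5.697-fold and 3.29-fold lower. Of 9050 genes 203 were higher and 150 lower. IGF2 and DLK1 also lead cluster 19 and APLN cluster 12, so they are not independent of the clustering. The arterial median was 0.14 with the mean of per-cell CPM.

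The share of endothelial-like cells with a UMI of GJA5, each cell thinned to 4000 UMIs, was 26.5% (25.4 to 27.6) in day6, 82.4% (81.0 to 83.8) in day12, 56.1% (53.8 to 58.5) in day19 and 66.8% (64.4 to 69.0) in day25a. Without thinning the shares were 41.2%, 90.1%, 67.4% and 81.4%. In haematopoietic-like cells, taken as background, the thinned shares were 9.51%, 4.45%, 4.76% and 6.29%, and in mesenchymal-like cells at most 8.46%. For DLL4 the endothelial shares were 51.04%, 54.5%, 55.3% and 61.5% (82.3%, 91.6%, 88.1% and 95.4% without thinning), against 17.5%, 1.27%, 1.15% and 1.93% in blood cells. The day6 blood shares are no firm background. Progenitor-like cells of day6 held the endothelial genes KDR at 326 CPM and CDH5 at 111 CPM, and DLL4 at 43.6 and GJA5 at 27.2 CPM. Epithelial-like cells of day6 held these 4 genes at 42.4, 13.1, 6.59 and 5.19 CPM. Thinning left out 111, 20, 109 and 31 endothelial-like cells with fewer UMIs. Median depths were 12334, 14780.5, 15907 and 18728.5 UMIs in endothelial-like cells and 15294, 21786, 12840 and 8867.5 in blood cells.

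Blood cells of day12 and day6 were compared next. Differences include makeup, since day6 blood was almost wholly progenitor-like and day12 blood also held myeloid-like and megakaryocyte-like cells. MHC class II genes, which present antigen, were all higher in day12, with a median log2 ratio of 5.29 (3.89 to 7.07; percentile 100) over 10 genes. With the 4 members at 0 counts in day6 placed at their bound the median was 5.41, and with a pseudocount of 5 CPM it was 3.88. HLA-DRA, with 0 counts in day6, stood at 892 CPM, at least 1316-fold higher, and CD74 at 498 against 2.71 CPM. Also higher were HBE1 350.4-fold and PF4 302-fold, with AHSP, a haemoglobin chaperone, PRTN3, a granule protease, and CLC, a granule protein of eosinophils and basophils, at least 133-fold, 106-fold and 105-fold higher over 0 counts. Of the haemogenic list 7 of 16 genes were higher and 2 lower (median 0.95, -0.06 to 1.38; percentile 100). The higher ones included the pan-leukocyte gene PTPRC at 156 against 10.8 CPM and the myeloid factor SPI1 at 157 against 74.1 CPM, and the lower ones CD44 at 273 against 582 CPM and MYCN at 42.2 against 143 CPM. RUNX1 stood at 85.3 against 159 CPM. Interferon response genes had a median of -0.33 (-4.39 to -0.13; percentile 12.8), with 1 of 11 higher and 5 lower, among them ISG15 at 129.6 against 1782 CPM and IFIT1 at 1.53 against 233 CPM. IGFBP5 was 140.2-fold lower and the endothelial genes LPL and TM4SF1 were 47.4-fold and 30.7-fold lower. Of 9179 genes 716 were higher and 1014 lower. With predicted doublets kept, when 0.958% of day6 cells were haematopoietic-like, the counts were 667 and 229.

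Blood cells of day15, nearly all lymphoid-like, were set against those of day12. T, NK and innate lymphoid genes had a median of 5.10 (3.82 to 5.65; percentile 100), with 13 of 16 higher and 2 lower. IL32, a cytokine of activated lymphocytes, stood at 6401 CPM, 6386 to 6415, against 22.1 CPM, 20.7 to 23.5, CD247 at 598 against 1.18 CPM, GZMB at 665 against 0.624 CPM and TRBC1 at 464 against 1.08 CPM. Lymphoid commitment genes had a median of 0.95 (-0.44 to 2.67; percentile 99.97), with 6 of 14 measured genes higher and 2 lower, among them RAG1 at 43.7 against 0.672 CPM and CD7, an early surface protein of T and NK cells, at 535 against 18.8 CPM. MHC class II genes were all lower (median -4.54, -4.82 to -3.75; percentile 0; 10 of 10). The stem cell signature had a median of -2.10 (-3.16 to -1.56; percentile 0.020), with 3 of 6 lower. Among the lower genes, PPBP stood at 1.03 against 2033 CPM, HBE1 at 3.52 against 983 CPM and the platelet glycoprotein GP9 at 0.109 against 224 CPM, and CD34, a marker of endothelium and blood progenitors, at 0.185 against 129 CPM. PF4 had 1 count in day15, against 1186 CPM in day12. GZMB also leads cluster 23 and RAG1 cluster 21. Of 9222 genes 1170 were higher and 1018 lower, against 985 and 1160 with median-of-ratios scaling (shift of all genes -0.12) and 1116 and 1350 without mitochondrial and ribosomal genes (shift -0.10), and the lower side was also larger with doublets kept and without a minimum CPM.

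Blood cells of day19, mostly myeloid-like, megakaryocyte-like and of cluster 13, were set against those of day15. Among the higher genes, PPBP stood at 1095 against 1.03 CPM, HBE1 at 1337 against 3.52 CPM, HLA-DRA at 2052 CPM, 2038 to 2066, against 24.6 CPM, 23.7 to 25.5 and HLA-DPA1 at 885 against 7.81 CPM. T, NK and innate lymphoid genes had a median of -3.45 (-3.59 to -2.55; percentile 0), with 2 of 16 higher and 13 lower. GZMB stood at 1.18 against 665 CPM, the T cell co-receptor chain CD8B at 0.123 against 54.2 CPM, and the hair keratin KRT81 at 0.739 against 212 CPM. GZMB and KRT81 lead cluster 23 and CD8B cluster 25. Of 9152 genes 903 were higher and 1236 lower, against 1117 and 891 with median-of-ratios scaling (shift of all genes 0.19) and 1249 and 1091 without mitochondrial and ribosomal genes (shift 0.13). With day15 left out, day19 differed from day12 in 367 genes, 199 higher and 168 lower, where day15 differed from day12 in 2188 and from day19 in 2139.

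Blood cells of day25a were set against those of day19, and differences include makeup. Cluster 13 held 42.1% of day25a and 19.3% of day19 blood, lymphoid-like cells were 15.7% and 2.63%, and erythroid-like cells 0.155% and 4.87%. Of 15 measured lymphoid commitment genes 11 were higher in day25a and 0 lower, with a median of 2.04 (1.28 to 2.42; percentile 100). RAG1 stood at 10.3 CPM, 9.26 to 11.5, against 0.985 CPM, 0.704 to 1.34, and its partner RAG2 at 15.6 against 1.06 CPM. IL7R, the interleukin 7 receptor that lymphoid progenitors need, stood at 127 against 16.7 CPM, CD7 at 369.9 against 68.5 CPM, LTB, a cytokine of lymphoid cells, at 2851 against 690.1 CPM, and IGLL1, a surrogate light chain of early B cells, at 157 against 63.8 CPM. T, NK and innate lymphoid genes had a median of 2.09 (1.41 to 2.45; percentile 100), with 11 of 16 higher and 1 lower (CD2, 7.06 against 38.9 CPM). CD3D stood at 1311 against 232 CPM, the gamma-delta receptor constant gene TRDC at 522 against 56.1 CPM, TRBC1 at 224 against 8.62 CPM and LCK at 186 against 22.9 CPM. The Notch list had a median of 0.73 (0.28 to 1.80; percentile 100), with 4 of 14 higher and 0 lower, HES4 at 271 against 52.8 CPM, NRARP at 20.9 against 5.27 CPM, DTX1 at 10.99 against 1.55 CPM and the receptor NOTCH3 at 17.1 against 3.79 CPM. HES4, NRARP and DTX1 belong to the lymphoid commitment list as well. Globins were all lower (median -2.59, -3.07 to -2.51; percentile 0; 8 of 8), with HBZ at 65.2 against 2359.6 CPM and HBG2 at 1484 against 8430.5 CPM, and PRTN3 was 12.97-fold lower. Of 8911 genes 378 were higher and 114 lower, against 278 and 163 with median-of-ratios scaling (shift -0.16). Set in its place, day25b differed from day19 in 1521 genes.

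Blood cells of day25b, most of them in clusters 22, 23 and 25, were set against those of day19. T, NK and innate lymphoid genes had a median of 3.03 (2.09 to 4.07; percentile 100), with 13 of 16 higher and 2 lower. GZMB stood at 593 CPM, 588 to 598, against 1.18 CPM, 0.871 to 1.57, TNFRSF18, a receptor of activated T and NK cells, at 339 against 1.65 CPM, and the kinase ZAP70 at 50.7 against 0.468 CPM. Lymphoid commitment genes had a median of -0.24 (-0.88 to 0.14; percentile 8.62), with 2 of 15 higher and 2 lower. CD7 stood at 294 against 68.5 CPM, while IGLL1 stood at 5.38 against 63.8 CPM and JCHAIN at 5.86 against 49.5 CPM. Cell cycle lists were higher, with medians of 1.03 (0.71 to 1.23; 7 of 14 higher) for S phase and 1.23 (1.03 to 1.39; 11 of 14 higher) for G2 and mitosis, both at percentile 100, and MKI67 at 339 against 107 CPM. Hypoxia and glycolysis genes had a median of 0.83 (-0.05 to 1.14; percentile 99.99), with 3 of 11 higher, including LDHA at 1002 against 432 CPM. Among the lower genes, CLC stood at 0.107 against 828 CPM, the eosinophil peroxidase EPX at 0.633 against 125 CPM and the IgE receptor chain FCER1A at 0.5796 against 88.6 CPM. Of 8917 genes 771 were higher and 750 lower, against 750 and 776 with median-of-ratios scaling and 794 and 1022 without mitochondrial and ribosomal genes, so neither side is read as larger.

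Both day 25 libraries were then set against each other. In whole libraries, COL1A1 stood in day25a at 2325 against 0.665 CPM, COL4A1 at 1887 against 0.279 CPM and fibronectin FN1 at 3159 against 2.91 CPM. AHSP was 168-fold lower, KRT81 148-fold lower and GZMB 40.6-fold lower. Of 9918 genes 2089 were higher and 969 lower, and median-of-ratios scaling shifted the median of all genes by -0.14. Differences between their blood cells include makeup, with myeloid-like cells at 31.5% of day25a and 2.30% of day25b blood and lymphoid-like cells at 15.7% and 83.4%. In blood cells, MHC class II genes were higher in day25a (median 3.61, 3.26 to 3.77; percentile 100; 10 of 10). CLC stood at 393 against 0.107 CPM, FCER1A at 76.8 against 0.5796 CPM, S100A8, a calcium-binding protein of myeloid cells, at 141 against 3.81 CPM and IGLL1 at 157 against 5.38 CPM. T, NK and innate lymphoid genes had a median of -0.46 (-1.32 to -0.19; percentile 0.0700), with 2 of 16 higher and 6 lower, and GZMB stood at 37.5 against 593 CPM. AHSP stood at 8.39 against 617 CPM and APOE at 8.204 against 158 CPM. Genes of other compartments were also higher in day25a blood cells. The extracellular matrix list had a median of 3.55 (1.97 to 4.41; percentile 100; 8 of 14 higher), with COL4A1 at 62.8 CPM against 0 counts, at least 1952-fold higher. With its 2 members at 0 counts placed at their bound this median was 3.65, and with a pseudocount of 5 CPM it was 1.66. The arterial list had a median of 2.16 (percentile 100; 7 of 19 measured higher). SOX17 and IGFBP3 of this list had 0 counts in day25b, and its median was not taken again with them at their bound. Day25a held endothelial-like and mesenchymal-like cells in the same suspension, and day25b held 0 and 1. Of 9154 genes in blood cells 863 were higher and 421 lower, against 737 and 602 with median-of-ratios scaling (shift -0.15). With day15 in the place of day25a, day25b differed in 401 genes in whole libraries and 402 in blood cells, where against day25a the counts were 3058 and 1284.

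Shares of blood cells with a UMI were compared for genes of commitment, with cells thinned to 4000 UMIs and 3, 20, 295, 118, 277 and 152 shallower cells left out of day6, day12, day15, day19, day25a and day25b. RAG1, the recombinase gene that carries the reporter, had a UMI in 9.20% (8.60 to 9.83) of day15 blood cells, 3.99% (3.31 to 4.76) of day25a, 0.396% of day25b, 0.346% of day12, 0.324% of day19 and 0 of day6 cells, which allows up to 1.14%. Without thinning the day15 and day25a shares were 14.1% and 6.59%. Endothelial-like cells had RAG1 shares of 0.431% in day6, 0.587% in day12, 0.580% in day19 and 0.602% in day25a, mesenchymal-like cells at most 0.632%, and erythroid-like cells of day25b 0 (up to 0.552%). The day25a blood share lay above the endothelial-like share of its library. In day12 and day19 the blood intervals (0.127 to 0.752 and 0.148 to 0.615) overlapped the endothelial-like ones (0.342 to 0.938 and 0.278 to 1.06). The day19 mesenchymal-like share, 0.264% (0.0720 to 0.675), overlapped too, so no order is read in these libraries. The day19 myeloid-like share was 0 (up to 0.216%). Myeloid-like and erythroid-like cells are part of the blood cells, so for every gene here their shares are no separate background. In day12 the myeloid-like share was 0.387%. In day15 the 132 myeloid-like cells deep enough, with a median of 17820 UMIs, had a RAG1 share of 1.52% (0.184 to 5.37), below that of all its blood cells. IL7R had a UMI in 30.1% (28.4 to 31.8) of day25a, 12.8% of day15, 7.38% of day25b, 4.79% of day19 and 2.77% of day12 blood cells, against at most 0.783% of endothelial-like cells. The mesenchymal-like shares were 15.97% in day12, 13.5% in day19 and 8.87% in day25a, and the myeloid-like shares 7.35% in day12, 7.58% (3.69 to 13.5) in day15, 4.98% (3.89 to 6.26) in day19, 6.72% in day25a and 19.8% in day25b. The day12 blood share lay below both, the day19 share below the mesenchymal-like and within the myeloid-like interval, the day25b share below the myeloid-like, the day15 share within the myeloid-like interval, and the day25a share above both. Erythroid-like cells had IL7R shares of 0 in day19 (up to 2.24%) and day25b (up to 0.552%), below the blood shares of those libraries. Mesenchymal-like and myeloid-like cells may themselves express IL7R, so shares below theirs are not read as background. Unthinned, the day25a share was 40.0%. CD7 had a UMI in 73.9% of day15, 56.0% of day25b, 47.8% of day25a, 17.9% of day19, 6.52% of day12 and 0.760% of day6 blood cells, against at most 0.843% of endothelial-like cells, 2.26% of mesenchymal-like cells, 11.9% and 7.92% of erythroid-like cells of day19 and day25b and 11.4% of myeloid-like cells of day15. Its CPM stood higher in day25a than in day25b, so no order is read from those 2 shares. RUNX1 shares were 44.5% (38.4 to 50.7) in day6, 24.2% in day12, 3.12% in day15, 16.4% in day19, 12.95% in day25a and 2.92% in day25b. Unthinned they were 85.0% in day6, 8.35% in day15 and 10.6% in day25b. Other classes had RUNX1 shares of at most 9.27% in endothelial-like cells, 11.98% in epithelial-like cells of day6 and 18.97%, 14.5% and 10.5% in mesenchymal-like cells of day12, day19 and day25a. MYB, a progenitor transcription factor, had shares of 25.1% in day6, 14.4% in day12, 8.28% in day15, 18.3% in day19, 16.7% in day25a and 4.57% in day25b. Unthinned they were 63.2% in day6 and 14.4% in day25b. Its shares were at most 2.79% in endothelial-like cells and 0.462% in mesenchymal-like cells. Neither RUNX1 nor MYB fell steadily along the labels, and both were lowest in the lymphoid-rich day15 and day25b. GFI1, a repressor active in the endothelial-to-haematopoietic transition, had a UMI in 5.55% of day25a and 1.04% of day25b blood cells (13.5% and 3.77% unthinned), against at most 0.138% of endothelial-like and 0.237% of mesenchymal-like cells. The library with the largest GFI1 share depended on the setting, with 8.33% in day6 with doublets kept and 13.8% in day12 unthinned. HOXA9 had a UMI in 3.04% of day6 and 0.585% of day15 blood cells (8.65% and 1.43% unthinned), against 1.02% to 1.45% of endothelial-like, 3.71% of day6 epithelial-like and 4.42% of day25b erythroid-like cells. The day6 share was 0.755% at 2000 UMIs and 0.926% with doublets kept, so no order is read from it. DNTT, the terminal transferase of lymphoid progenitors, had no UMI in any blood cell after thinning, with the tightest limit 0.0344% in day15. Median blood cell depths were 15294, 21786, 11558, 12840, 8867.5 and 13060 UMIs. Mesenchymal-like cells had 23255, 23241 and 23780 in day12, day19 and day25a, epithelial-like cells of day6 16038, erythroid-like cells 19236 in day19 and 37622 in day25b, and myeloid-like cells 16328, 13424, 10464 and 22278 in day12, day19, day25a and day25b.

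**Figure D4:**
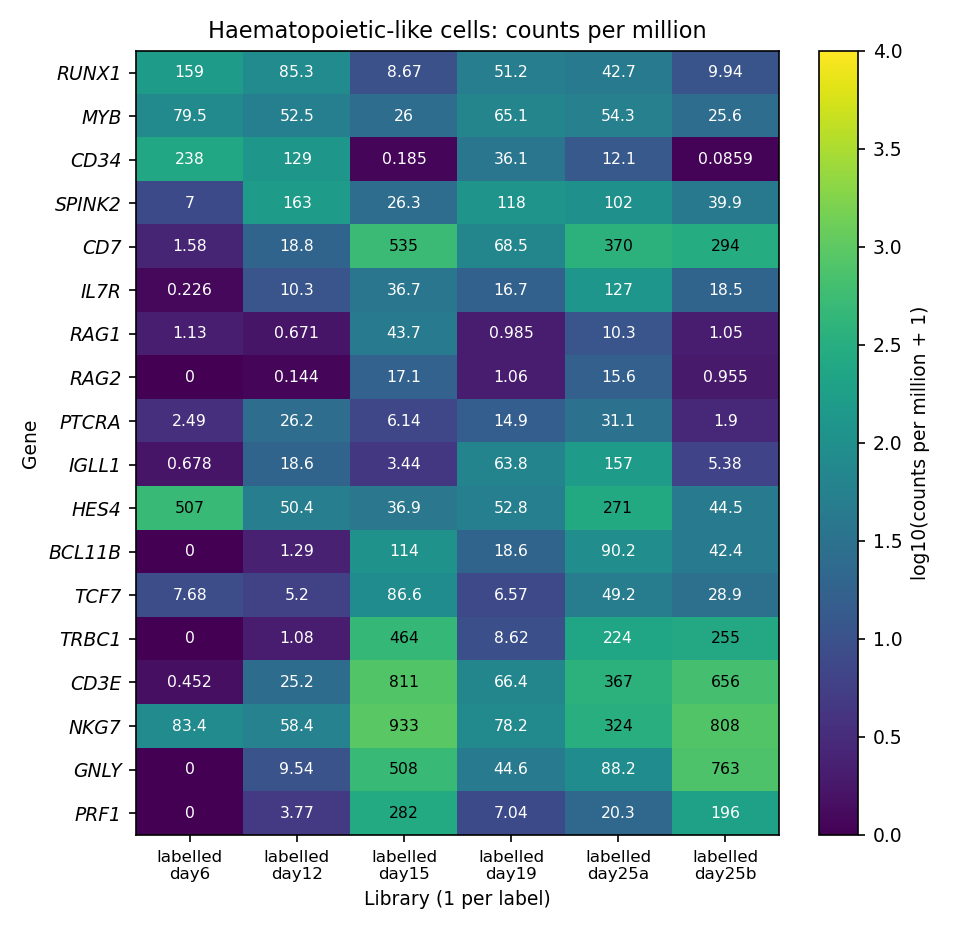
Each tile gives the CPM of a gene (vertical) in haematopoietic-like cells of a library (horizontal), coloured by the log10 of CPM plus 1. RAG1 stands highest in the library labelled day15 and IL7R in day25a.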

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

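The predictions behind all tests in this part were written after the patterns had been seen, and so were the clusters tested for mitosis, the split of the arterial genes by free RNA and its margin of 2 times, which replaced a first version without a margin. The comparison with mesenchymal RNA was added after that.

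In day12 against day6, the S phase list had a median log2 ratio of -1.37 in endothelial-like cells and 0.085 in haematopoietic-like cells, on opposite sides of 0. In day25a against day19, the G2 and mitosis list had a median of -2.24 in endothelial-like cells and 0.19 in haematopoietic-like cells. Both were picked out because the intervals of the 2 compartments lay on opposite sides of 0 and at least 1 median was 1 or more in size, a condition set after the medians were seen. These differences between compartments were not tested.

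The library labelled day15 held almost only lymphoid-like cells, while the library labelled day25a held endothelial-like and mesenchymal-like cells that the design text does not give for day 25. If the labels were right and only non-blood cells had been lost from day15, its blood cells would resemble those of day12 and day19, but 95.7% (95.3 to 96.1) were lymphoid-like, which argues against this; a sort for lymphoid cells stays open. An exchange of day15 with day25a alone, with a steadily growing lymphoid-like share, is argued against by the 15.7% (14.5 to 17.0) in day25a, above the 2.63% of day19. A rotation in which day15 was taken on day 25, day19 on day 15 and day25a on day 19 could account for the values: endothelial-like cells of day25a differed from day12 in 408 genes and those of day19 in 209. The labels as they stand predict that order too, so this only sets a rotation apart from the exchange. Blood cells of day15 differed from day25b in 402 genes, from day12 in 2188 and from day19 in 2139. A rotation and a sort of day15 for lymphoid cells could each give these counts, so they do not choose between the 2. An error in the labels remains a hypothesis.

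In blood cells 7 of 19 measured arterial genes were higher in day25a than in day25b, and RNA released by endothelial cells in the same suspension is a candidate source, since the 10th and 90th percentiles of 49 reference genes of endothelial cells in day25a blood cells were 1.87% and 4.52% of their endothelial level. GJA5 and EFNB2, at up to 2.87%, lay between these percentiles, as free RNA predicts. GJA4, at 6.90%, and CXCR4, at 4.555%, lay above the 90th percentile by less than 2 times, so this rule leaves both open. Their excess over day25b, not part of the prediction for these genes, was 1.45 and 0.611 times what endothelial and mesenchymal RNA together give at the 90th percentiles. For CXCR4 free RNA could thus account for the excess. NOTCH1 and HES4 stood at 36.8% or more, and their excess over day25b was at least 4.99 times what endothelial and mesenchymal RNA together give at the 90th percentiles, which argues against free RNA as their whole source. Blood cells of day25b, a library with 0 endothelial-like cells and 1 mesenchymal-like cell, held NOTCH1 at 26.2 CPM and HES4 at 44.5 CPM. Blood cells thus held RNA of both genes without these neighbours. In cluster 13 of day25a HES4 stood at 446 CPM, above its 336.9 CPM in endothelial-like and 348.2 CPM in mesenchymal-like cells. Free RNA of these cells alone could not give a level above their own, for HES4. Cluster 13 made up 42.1% of day25a and 3.43% of day25b blood. Makeup and higher expression within blood cells were not told apart, and that either made the day25a excess remains a hypothesis. For LTBP4 the excess over day25b was 1.61 times what both kinds of RNA give, too small to decide.

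Of 14 genes of the G2 and mitosis list 13 were lower in endothelial-like cells of day25a than of day19, and different clusters held most of these cells. Within cluster 12 (278 and 707 cells) the median of the G2 and mitosis list was -2.35 (-2.63 to -2.20), which argues against cluster makeup as the whole cause. Within cluster 19 (1401 and 224 cells) it was -0.56 (-1.22 to -0.04), too small a difference to decide. Time in culture, which the labels name, stays open as a biological explanation, and it was not tested.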

How the results depend on the processing

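The alternatives that leave out day15 or day25a were chosen after the data were seen, although day25b against day19, used as one of them, was itself a planned comparison, and the other alternatives were planned. Calls of single genes were not taken through the alternatives. Of the 37 list medians only that of the Notch pathway in endothelial-like cells, day12 against day6, changed sign, at 0.02 without mitochondrial and ribosomal protein genes and 0.08 with the mean of per-cell CPM. The stricter cell filter kept 13 of 13 gene counts within 1.5 times and 37 of 37 list medians within their intervals, and CPM without mitochondrial and ribosomal protein genes did the same. The intervals of list medians measure spread between members and can be wide, above all in short lists. A median kept within its interval is therefore weak evidence that it is stable. The balance of genes higher and lower turned in haematopoietic-like cells of day15 against day12 and day19 against day15 with median-of-ratios scaling and without mitochondrial and ribosomal protein genes, and both also turned without a minimum CPM. It turned with doublets kept for day12 against day6 and day15 against day12, and the near-even balance of day25b against day19 turned under these settings, the stricter filter and a pseudocount of 5 CPM. In endothelial-like cells it turned for day19 against day12 with median-of-ratios scaling. Median-of-ratios scaling and the mean of per-cell CPM also kept 13 of 13 counts, and a pseudocount of 5 CPM and kept doublets 12 of 13 each. Median-of-ratios scaling kept 36 of 37 list medians, kept doublets 35, the pseudocount 33 and the mean of per-cell CPM 31. Of class shares 19 of 42 were unmoved at 1500 variable genes, 27 of 42 at resolution 0.5 and 21 of 37 at resolution 2.0, and 26 of 42 under the stricter filter and 32 of 42 with doublets kept. At resolution 2.0 day6 had fewer than 100 blood cells and gave no shares within blood. Of 56 shares of cells with a UMI, 54 were unmoved with doublets kept, 12 at 2000 UMIs and 8 without thinning. Depth limits the day6 blood cells most, with 4425838 UMIs in 266 cells. Where no cause is named, the cause was not tested.

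With predicted doublets kept, the haematopoietic-like share of cells was 0.958% in day6. The endothelial-like share of cells was 51.9% in day6, 45.7% in day12 and 27.3% in day19. The progenitor-like share of blood cells was 0% in day25b. The erythroid-like share was 4.62% in day12, 8.36% in day19 and 0.422% in day25a. The megakaryocyte-like share was 0.0107% in day15 and 17.2% in day19. The G2 and mitosis median in endothelial-like cells, day25a against day19, was -1.72 where it had been -2.24. The extracellular matrix median in haematopoietic-like cells, day25a against day25b, was 4.83 where it had been 3.55. In haematopoietic-like cells, day12 against day6 gave 896 genes where it had been 1730. The GFI1 share in day6 blood cells was 8.33%. The HOXA9 share in day6 blood cells was 0.926%.

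At Leiden resolution 0.5, the haematopoietic-like share of cells was 0.973% in day6. The endothelial-like share of cells was 56.1% in day6. The lymphoid-like share of blood cells was 96.4% in day15 and 19.7% in day25a. The progenitor-like share was 0 in day6, day12, day15, day19, day25a and day25b. The myeloid-like share was 96.3% in day6, 64.4% in day12, 1.98% in day15, 52.5% in day19 and 3.36% in day25b.

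At Leiden resolution 2.0, the haematopoietic-like share of cells was 0.427% in day6 and 99.5% in day25b. The endothelial-like share of cells was 56.4% in day6. The lymphoid-like share of blood cells was 94.1% in day15, 5.105% in day19, 40.04% in day25a and 80.7% in day25b. The progenitor-like share was 43.3% in day12, 3.44% in day15, 27.8% in day19, 21.4% in day25a and 6.62% in day25b. The megakaryocyte-like share was 0.704% in day25b. The myeloid-like share was 24.5% in day12, 39.9% in day19 and 29.02% in day25a.

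Under the stricter cell filter, the haematopoietic-like share of cells was 26.6% in day12. The endothelial-like share of cells was 26.8% in day19 and 25.98% in day25a. The progenitor-like share of blood cells was 98.5% in day6 and 43.5% in day12. The erythroid-like share was 6.25% in day19 and 10.9% in day25b. The megakaryocyte-like share was 0.3802% in day6, 24.1% in day12, 0.0275% in day15, 16.99% in day19 and 8.37% in day25a. The myeloid-like share was 25.3% in day12, 2.19% in day15, 46.6% in day19 and 3.905% in day25b.

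With 1500 variable genes and 30 components, the lymphoid-like share of blood cells was 1.54% in day12, 97.004% in day15, 16.65% in day19, 55.5% in day25a and 85.6% in day25b. The progenitor-like share was 0.0222% in day15, 8.77% in day19 and 1.98% in day25a. The erythroid-like share was 5.71% in day6, 23.7% in day12, 1.11% in day15, 23.4% in day19 and 3.7998% in day25a. The megakaryocyte-like share was 0.357% in day6, 16.3% in day12, 0% in day15, 11.9% in day19 and 8.804% in day25a. The myeloid-like share was 0% in day6, 24.1% in day12, 1.86% in day15, 39.3% in day19 and 3.38% in day25b.

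A minimum of 50 CPM leaves fewer genes that can be counted, and this lowers every count by construction. In whole libraries there were 359 for day12 against day6, 1366 for day15 against day12, 1384 for day19 against day15 and 1199 for day25a against day25b. In endothelial-like cells there were 440 for day12 against day6, 86 for day19 against day12 and 121 for day25a against day19. In haematopoietic-like cells there were 626 for day12 against day6, 826 for day15 against day12, 840 for day19 against day15, 157 for day25a against day19, 533 for day25b against day19 and 407 for day25a against day25b. Without a minimum more genes enter. Whole libraries then had 1957 for day12 against day6, 5253 for day15 against day12, 5331 for day19 against day15 and 4834 for day25a against day25b. Endothelial-like cells had 1673 for day12 against day6, 389 for day19 against day12 and 704 for day25a against day19. Haematopoietic-like cells had 3032 for day12 against day6, 3811 for day15 against day12, 3671 for day19 against day15, 909 for day25a against day19, 2839 for day25b against day19 and 2578 for day25a against day25b.

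With median-of-ratios scaling, the Notch pathway median in endothelial-like cells, day12 against day6, was -0.085 where it had been -0.01. With the mean of per-cell CPM, the S phase median in endothelial-like cells, day12 against day6, was -1.60 where it had been -1.37. The arterial endothelium median in endothelial-like cells, day19 against day12, was -0.12 where it had been -0.29. The arterial endothelium median in endothelial-like cells, day25a against day19, was 0.14 where it had been 0.33. The MHC class II median in haematopoietic-like cells, day15 against day12, was -6.00 where it had been -4.54. The embryonic and fetal globins median in haematopoietic-like cells, day25a against day19, was -2.31 where it had been -2.59. The MHC class II median in haematopoietic-like cells, day25a against day25b, was 3.91 where it had been 3.61. With a pseudocount of 5 CPM, the G2 and mitosis median in endothelial-like cells, day25a against day19, was -1.60 where it had been -2.24. The MHC class II median in haematopoietic-like cells, day12 against day6, was 3.88 where it had been 5.29. The blood stem cell signature median in haematopoietic-like cells, day15 against day12, was -1.41 where it had been -2.10. The extracellular matrix median in haematopoietic-like cells, day25a against day25b, was 1.66 where it had been 3.55. In endothelial-like cells, day19 against day12 then gave 139 genes where it had been 209. A larger pseudocount pulls ratios of low genes towards 0 by construction.

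Leaving out day15 gave 243 genes for day19 against day12 in whole libraries, where day15 against day12 had 3338 and day19 against day15 3386, and 367 in haematopoietic-like cells, where these had 2188 and 2139. Day25b differed from day15 in 401 genes in whole libraries and 402 in haematopoietic-like cells, where it differed from day25a in 3058 and 1284. Without day25a, day25b differed from day19 in 1521 genes in haematopoietic-like cells, where day25a had differed in 492.

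Thinning to 2000 UMIs gives each cell fewer chances of a UMI and lowers shares by construction. The GJA5 share of endothelial-like cells was 17.8% in day6, 72.96% in day12, 44.9% in day19 and 54.4% in day25a. The DLL4 share of endothelial-like cells was 30.6% in day6, 34.7% in day12, 33.4% in day19 and 40.1% in day25a. The RUNX1 share of haematopoietic-like cells was 32.1% in day6, 14.8% in day12, 1.83% in day15, 10.1% in day19, 8.31% in day25a and 1.79% in day25b. The RAG1 share of haematopoietic-like cells was 7.93% in day15, 0.1401% in day19 and 2.51% in day25a. The IL7R share of haematopoietic-like cells was 7.79% in day15, 2.73% in day19, 18.998% in day25a and 4.55% in day25b. The CD7 share of haematopoietic-like cells was 0 in day6, 3.28% in day12, 57.3% in day15, 11.7% in day19, 35.8% in day25a and 40.02% in day25b. The MYB share of haematopoietic-like cells was 18.5% in day6, 8.45% in day12, 5.29% in day15, 10.6% in day19, 9.13% in day25a and 2.96% in day25b. The GFI1 share of haematopoietic-like cells was 0.755% in day6, 1.96% in day12, 1.504% in day15, 1.68% in day19, 3.93% in day25a and 0.6903% in day25b. The HOXA9 share of haematopoietic-like cells was 0.755% in day6, 1.09% in day12, 0.326% in day15, 0.603% in day25a and 1.11% in day25b.

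Without thinning, deeper cells have more chances of a UMI, which makes shares higher by construction. The GJA5 share of endothelial-like cells reached 41.2% in day6, 90.1% in day12, 67.4% in day19 and 81.4% in day25a. The DLL4 share of endothelial-like cells reached 82.3% in day6, 91.6% in day12, 88.1% in day19 and 95.4% in day25a. The RUNX1 share of haematopoietic-like cells reached 84.96% in day6, 64.8% in day12, 8.35% in day15, 38.8% in day19, 27.4% in day25a and 10.6% in day25b. The RAG1 share of haematopoietic-like cells reached 1.88% in day6, 1.598% in day12, 14.1% in day15, 1.24% in day19, 6.59% in day25a and 0.806% in day25b. The IL7R share of haematopoietic-like cells reached 8.11% in day12, 23.9% in day15, 10.1% in day19, 39.95% in day25a and 15.6% in day25b. The CD7 share of haematopoietic-like cells reached 23.5% in day12, 87.2% in day15, 33.3% in day19, 57.5% in day25a and 76.3% in day25b. The MYB share of haematopoietic-like cells reached 63.2% in day6, 43.4% in day12, 17.3% in day15, 39.1% in day19, 28.9% in day25a and 14.4% in day25b. The GFI1 share of haematopoietic-like cells reached 11.3% in day6, 13.8% in day12, 6.92% in day15, 10.3% in day19, 13.5% in day25a and 3.77% in day25b. The HOXA9 share of haematopoietic-like cells reached 8.65% in day6, 7.65% in day12, 1.43% in day15, 3.11% in day19, 3.46% in day25a and 5.64% in day25b.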

Other observations

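The cell groups and genes in this part were chosen after their values were seen, and no test was run on them.

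The progenitor-like cells of day6 (257 cells of cluster 5) carried RNA of a few interferon-responsive genes at high levels. ISG15, a ubiquitin-like modifier, stood at 1845 CPM (95% interval 1804 to 1886), against 319 in endothelial-like and 119 in epithelial-like cells of day6 and 121 in progenitor-like cells of day12. IFIT1, which binds foreign RNA, stood at 242 CPM (228 to 257), against 11.6, 1.85 and 1.39 in the same order, and IFIT3 at 248 CPM (234 to 264), against 44.3, 7.64 and 5.40. IFIT2 stood at 67.5 CPM (59.9 to 75.8), against 2.78, 0.495 and 1.09. In the day6 progenitor-like cells MX1 stood at 1.87 CPM, IFI6 at 11.2 and IFI27 at 1.17, against 1.45, 12.8 and 2.08 in day6 endothelial-like cells and 3.27, 6.49 and 0.644 in day12 progenitor-like cells. OAS1 stood at 4.69 CPM (2.86 to 7.24), against 0.918 and 5.99 in these cells, and IFITM1 at 11.01 CPM (8.09 to 14.6), against 1.08 and 25.4. The day6 progenitor-like cells also held CD3D, a chain of the CD3 complex that signals for the T cell receptor, at 293 CPM (277 to 309). CD3E, its partner chain, stood at 0.469 CPM (0.0568 to 1.69).

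Genes of lymphoid commitment differed between clusters of day15 and day25a. RAG1 stood at 837 CPM (807 to 867) in cluster 21 and 182 CPM (172 to 192) in cluster 20 of day15, and at 18.8 CPM (16.4 to 21.4) in cluster 13 and 19.8 CPM (15.8 to 24.6) in cluster 20 of day25a. RAG1 is the leading gene of cluster 21, so its level there is partly set by the clustering. RAG2 stood at 238 CPM in cluster 21 of day15 and 30.8 CPM in cluster 13 of day25a, and PTCRA, which encodes the pre-T cell receptor alpha chain, at 58.1 and 39.0 CPM in the same cells. Within cluster 13 these genes stood lower in day15, with RAG1 at 6.28 CPM (3.01 to 11.6), RAG2 at 4.399 and PTCRA at 5.66. In cluster 20 PTCRA was also lower in day15, at 11.5 CPM (9.23 to 14.3) in day15 and 33.2 CPM (27.9 to 39.2) in day25a. RAG1 went the other way there, at 182 CPM in day15 and 19.8 CPM in day25a. The Notch-responsive gene HES4 stood at 20.4 CPM (17.3 to 23.9) in cluster 20, 6.98 CPM (4.52 to 10.3) in cluster 21 and 122 CPM (105 to 140) in cluster 13 of day15, and 446 CPM (434 to 458) in cluster 13 and 417 CPM (398 to 437) in cluster 20 of day25a. DTX1, another Notch target, stood at 24.8 CPM (20.3 to 30.1) in cluster 20 of day25a and 3.36 CPM (2.17 to 4.95) in cluster 20 of day15. The early B cell factors EBF1 and PAX5 did not exceed 0.279 CPM in any of these cells, with 0 counts of both in cluster 13 of day15, which allows up to 1.89 CPM.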
